A study of Mus musculus with 8 samples.

How the data were processed

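Per the labels, total RNA was isolated from the brain of each mouse with a column kit, reverse transcribed, labelled indirectly with Cy3 or Cy5 and hybridised to 2-colour cDNA arrays. Each of 4 mutant mice was hybridised on 2 arrays against a wildtype pool, with the mutant in Cy5 on one and in Cy3 on the other. The series' design counts 4 wildtype mice in the pool, while the labelling protocol gives another number of control animals. Scanner, image software, background correction and normalisation are not given in the sources used here.

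The deposited table holds 20794 spots on 8 arrays as log2 ratios of the channels, with 1 additive constant per array. The log2 scale was inferred from the deposited values, since weak spots recur at ratios of small whole numbers, and the constants from the same values. The median deposited log2 ratio was -0.15, -0.03, -0.0045 and -0.03 on the arrays with the mutant in Cy5 (mice 1 to 4) and -0.57, -0.28, -0.13 and -0.09 on those with the mutant in Cy3. Without the array constant the median ratios were 1, 1.35, 1.12 and 1.23 in the first orientation and 0.803, 0.652, 0.68 and 0.578 in the second. The centring rule and the numerator of the ratio stay unknown. Values equal to log2 of 100000 plus the array constant (1 to 30 per array) are a code for an empty denominator and were treated as missing, as were 221 to 553 empty cells per array. All columns of values were used. No spot intensities were used here, so weak spots were recognised only from ratios of whole numbers up to 10. These were matched within 0.001 on the log2 scale (4.76% to 8.73% of values per array). Ordinary ratios can fall within that bound by chance, and how often was not estimated, so a matched spot need not be weak.

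Each mouse's 2 arrays were averaged, and limma 3.58.1 (R 4.3.3; lmFit and eBayes, intercept only) tested the 4 mouse means against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe needed a value in every mouse, which left 20595. Arrays were not turned, since the rule fixed for the direction of the ratios gave a value above 0. The effect of the dye, here the swap component, was tested the same way on 18797 probes with values on all 8 arrays. Because the pool was the only control, its RNA counts as 1 sample. Standard errors of probes and genes are the moderated ones of limma, which borrow spread from all probes or genes. They differ from those of the 4 mice alone.

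The platform annotation pairs 12771 spots with 1 gene symbol, none with several and 8023 with none. All 12771 were found in the RefSeq gene table (assembly GRCm38.p6) by gene identifier and carry its symbols. Names were first read at the same spot number. Probes of one gene then did not resemble each other, and a scan of 201 shifts of up to 100 spots found agreement at 11 alone. In windows of 800 spots the shift of 11 gave the highest rho by a margin of 0.02 in 25 of 26 windows (rho 0.15 to 0.362). In the last window it gave 0.148 against 0.146 for the next shift, so the annotation of the last 794 spots was not used. The shift named 12131 spots of 8653 genes. This naming was chosen after the values were seen. The lists below were also tested with names at the same spot number, as an alternative.

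Gene lists were fixed before the data were examined: editing enzymes and edited transcripts, glutamate, GABA and monoamine genes, ion channels, synaptic vesicle, immediate early, interferon, heat shock, glucocorticoid, circadian, cholesterol, mitochondrial and ribosomal genes, and markers of cell types and brain regions. Probes of a gene were averaged, and camera with a preset correlation of 0.01 tested the 31 lists with at least 3 measured genes (8604 genes in the mean ratio). Estimated correlations, fry and adjustment over the list alone were added. Genes within 20 Mb of the targeted loci were compared with all contiguous windows of as many genes.

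Named genes followed a rule fixed together with the lists: every probe of Adarb1 and Gria2, and up to 12 genes per direction with the largest mean among probes past the threshold with the same sign on all 8 arrays. The rule also named every member of a list past the threshold. That would have named 197 genes, so the text was narrowed afterwards to at most 2 members per list with the largest absolute mean, with a few further members of the editing lists, and gives the others as counts. Unnamed spots appear by number, 2 per direction. The same rule was applied to the swap component with array medians subtracted, where the sign had to be the same on all 8 arrays after it was turned on those with the mutant in Cy3.

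Chosen after the data were seen were the naming shift, the subtraction of medians for the swap component and the tests of gene lists and named genes on it. The same goes for the removal of a loess trend (span 0.3, degree 1) of each mouse's swap component on the mean ratio of the other mice, for the centring of runs of 48 spots, for the separation of mice 1 and 2 from mice 3 and 4, and for the comparison of spots coded for an empty denominator, which replaced one of empty cells after that one had been seen. Alternatives fixed together with the lists were other centring, scaling and quantile normalisation, single dye orientations, a dye term, the mouse as a random block in 8-array fits, each mouse or array left out, robust and plain tests, a SAM-type statistic and filters.

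The scripts were tested on simulated data. With 67, 67 and 66 of 20595 probes changed by 1.5-, 2- and 3-fold and the spread of these mice, none was recovered, though the mean estimates were 0.58, 1.00 and 1.62 for true log2 values of 0.58, 1.00 and 1.58. With a large part of the probes changed, 47.1%, 77.4% and 89.8% were recovered at these sizes, with 180 false among 5084 calls, and with no change there was no call. A shift of 0.5 added to 58 ribosomal genes was found as the only called list of 31. In these simulations the noise was drawn independently for each probe or gene. They therefore do not test the preset correlation, nor effects that many probes share. A simulated shift of 7 spots was found as 7. For the direction rule, simulated ratios that run the same way gave 0.124 and ratios by dye gave -0.129. Correlations and permutations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.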

Results

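Brain RNA of 4 male mutant mice, 19 weeks old, was compared with a pool of brain RNA from wildtype males of the same age on 2-colour cDNA arrays. The mutants lack ADAR2, the adenosine deaminase that edits double-stranded RNA in the brain and is encoded by Adarb1. They also carry Gria2 alleles that encode the arginine form of the GluR-B subunit of AMPA receptors, the form that editing by ADAR2 otherwise produces. Each mouse was hybridised on 2 arrays with the dyes exchanged, which gave 8 arrays, and the mouse was the replicate (n = 4). The design asks which transcripts differ between the brains of these mutants and of wildtype mice. The 8 arrays held 20211 to 20559 usable log2 ratios each, out of 20794 spots. Spot intensities were not used here, so the precision of a value rests on the number of mice and arrays. The pool is a single control sample, and the tests against it leave out the spread between wildtype mice.

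The labels give the dye of each RNA but not which channel is the numerator of the deposited ratio. Results are therefore given for 2 quantities. The mean ratio is the average of a mouse's 2 arrays as deposited, and it is the contrast of mutant and pool if all ratios run the same way. The swap component is the value with the mutant in Cy5 minus the value with the mutant in Cy3, divided by 2. It is the contrast of mutant over pool if the deposited ratios are Cy5 over Cy3, and the effect of the dye if they all run the same way. Signs below are those of the deposited values, and no direction of mutant against wildtype is settled.

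Gene names were read with a shift of 11 spots between the annotation and the values. At the same spot number, the mean ratios of 2 probes of a gene were unrelated (Spearman rho = -0.00143 across 2754 genes). At the shift of 11 rho was 0.274 for the mean ratio and 0.259 for the swap component, and the next highest of the 201 shifts tried gave 0.0888 and 0.11. Genes are not independent replicates, so these values are descriptions. The shift was found in the data and not in the labels, and all gene names below depend on it.

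**Figure D1:**
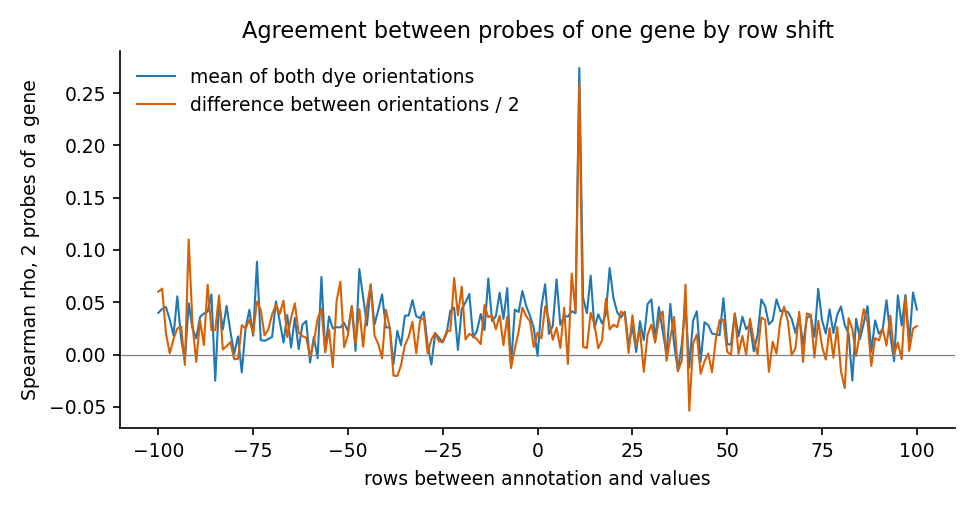
Spearman's rho between the values of 2 probes of a gene (vertical axis) against the number of spots by which the annotation was moved (horizontal axis), for the mean ratio and the swap component. Both lines peak at a shift of 11, at 0.274 and 0.259, and stay at or below 0.11 elsewhere.

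Adarb1, the disrupted gene, was measured by 3 probes, all with values on 8 arrays. Its swap component was -1.23 ± 0.163 (moderated SE of limma, n = 4) for probe 18422, with the mice at -1.61, -1.46, -0.92 and -0.95. It was -1.33 ± 0.267 for probe 18759, with the mice at -0.63, -2.24, -0.98 and -1.46. Both passed the limma test with array medians subtracted (adjusted p = 0.0383 and 0.0424) and missed it as deposited (adjusted p = 0.0591 and 0.0642). Probe 14946 stood at -0.10 ± 0.127 (adjusted p = 0.628). Among 18797 probes ordered from the most negative swap component, probes 18759 and 18422 ranked 4 and 8. Neither kept one sign on all 8 arrays once those with the mutant in Cy3 were turned. The other genes named below for this component had to.

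The mean ratio of Adarb1 passed in none of its probes as deposited. It was 0.54 ± 0.205 for probe 18422 (adjusted p = 0.0962), 0.09 ± 0.464 for probe 18759 (adjusted p = 0.885) and -0.04 ± 0.147 for probe 14946 (adjusted p = 0.828, limma). With array medians subtracted, probe 18422 reached 0.70 (adjusted p = 0.0297). Which part of the transcript the probes cover is not given in the sources used here, so a probe outside the disrupted part would check nothing. For Gria2, whose alleles in the mutants encode the arginine form, the shift was not certain at the end of the array. Spot row20589, its place if the shift held there too, had a mean ratio of 0.83 ± 0.196 (adjusted p = 0.0308) and a swap component of -0.29 (adjusted p = 0.205, medians subtracted). Spot row20578, its listed place, had a mean ratio of -0.79 ± 0.344 (adjusted p = 0.131).

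The direction of the ratios was examined by asking whether the 2 arrays of a mouse deviate together from the other arrays of their dye orientation. The correlation across 18797 probes was 0.133 on average for arrays of the same mouse. The exact permutation test over the 24 matchings of arrays to mice gave a one-sided p of 0.0417, the smallest it can give. By the rule fixed beforehand, a value above 0 was to mean that the ratios run the same way on all arrays. Restricted to mice 1 and 2 and to mice 3 and 4, whose arrays resembled each other, the correlation was 0.0264 (one-sided exact p = 0.25, the smallest possible with 4 matchings). The difference between these sets of mice was unrelated between 2 probes of a gene (rho = 0.00692, 95% interval -0.0333 to 0.0483). An effect tied to spots that also differs between mice, or between these sets, would give a value above 0 under ratios of Cy5 over Cy3 too. The rule therefore cannot decide the direction. Adarb1, low in the swap component and not in the mean ratio, points the other way, to ratios of Cy5 over Cy3. The direction therefore stays open, and the swap component gives a lower level of Adarb1 in the mutants only on that reading. If all ratios were pool over mutant, the mean ratio of probe 18422 (0.70, medians subtracted) would also be a lower level. The other probes of Adarb1 did not pass there.

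Fth1, the heavy chain of the iron store ferritin, had the largest positive mean ratio among genes past the threshold with the same sign on all 8 arrays. It stood at 1.33 ± 0.197 (moderated SE, n = 4, limma adjusted p = 0.0158). Calm2 and Calm3, which encode calmodulin, stood at 1.22 ± 0.179 and 1.12 ± 0.167, with swap components of -0.92 and -0.65 (adjusted p = 0.0383 for each, medians subtracted). Chn1, a neuronal regulator of Rac, had 1.18 ± 0.162, and Atp1b1, a subunit of the sodium-potassium pump, had 1.13 ± 0.191. At the other end stood Acbd3, a Golgi protein, at -3.58 ± 0.714, and Acsm3, an acyl-CoA synthetase, at -2.89 ± 0.547. Npm2, the nucleoplasmin of oocytes, had -2.23 ± 0.188, and Prss21, a serine protease of testis, had -2.11 ± 0.314.

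The other positive genes named by the fixed rule were the immunophilin Fkbp1a (1.22), the muscle kinase Speg (1.25), the endoplasmic reticulum protein Serp1 (1.21), the mitochondrial ribosomal protein Mrpl49 (1.20), the heme synthesis enzyme Ppox (1.16), the ribosomal protein Rpl26 (1.16) and the RNA helicase Ddx1 (1.12). The other negative genes were the catenin Ctnna3 (-2.26), Erh (-2.24), the mitochondrial dicarboxylate carrier Slc25a10 (-2.24), the semaphorin receptor Nrp2 (-2.22), Osbpl11 (-2.21), 1810055G02Rik (-2.20), the peptidase Dpp3 (-2.15) and Sltm (-2.14). Their adjusted p lay between 0.0153 and 0.0354. Of these 24 genes, 14 had other probes, 21 in all. For the positive genes 8 of 10 other probes passed with the same sign, and for the negative genes 3 of 11, all of Ctnna3. The other probe of Serp1 stood at -0.10 (adjusted p = 0.719) and that of Mrpl49 at 0.04 (0.953). The other probe of Acbd3 stood at -0.47 (adjusted p = 0.0865), that of Sltm at -0.05 (0.871), that of Slc25a10 at -2.13 (0.0936), those of Nrp2 at -0.48 (0.0835) and 0.24 (0.35), that of Erh at 0.000875 (0.997), a further one of Ctnna3 at -0.16 (0.581) and that of 1810055G02Rik at 0.15 (0.632). Of the 12 positive genes all had a negative swap component, from -0.92 to -0.41, and 7 passed there with medians subtracted, among them Fth1 (-0.59, adjusted p = 0.0403), Chn1 (-0.88, 0.0383) and Atp1b1 (-0.75, 0.0383). Of the 12 negative genes 9 had a positive swap component and 1 passed, Prss21 (0.97, adjusted p = 0.0385). Acbd3, Acsm3 and Npm2 had 0.11, 0.36 and 0.40 (lowest adjusted p = 0.345). On the reading of Cy5 over Cy3 these values, and not the mean ratios, would be the contrast of mutant over pool. Opposite signs in both quantities can also follow from the larger spread with the mutant in Cy3 (standard deviation 0.904, against 0.521 in Cy5). Among spots with no gene name that met the same rule, row17380 (1.33) and row20765 (1.31) had the largest positive values and row10049 (-2.67) and row19781 (-2.56) the largest negative ones.

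**Figure D2:**
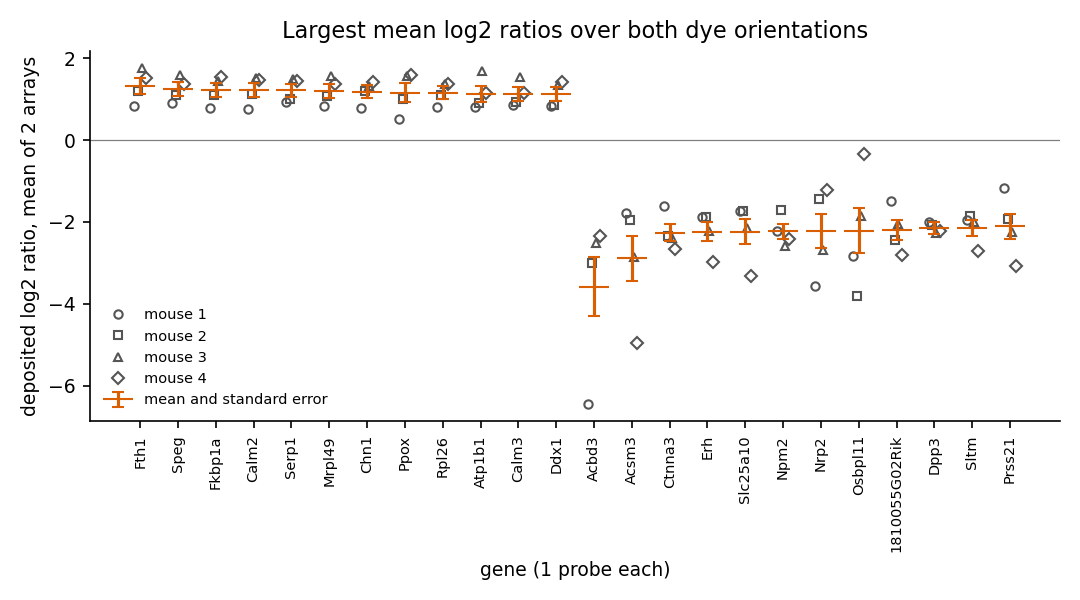
Deposited log2 ratio, averaged over the 2 arrays of each mouse (vertical axis), for the 12 genes with the largest positive and the 12 with the largest negative mean ratio among probes past the threshold with the same sign on all 8 arrays (horizontal axis, 1 probe each). Symbols are the 4 mice, bars are means with moderated standard errors. Positive genes lie between 1.12 and 1.33, and Acbd3, at -3.58, spreads most because mouse 1 stood at -6.44.

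Over all 20595 probes tested, limma called 6105 at an adjusted p below 0.05, 2286 with a positive and 3819 with a negative mean ratio. With array medians subtracted the count was 6256 and positive calls made up 56.1% in place of 37.4%, as the median of all probes moved from -0.25 to -0.09. The count fell to 0 without mouse 2, mouse 3 or mouse 4 (7380, 7721 and 8033 probes at an unadjusted p below 0.05), and also to 0 from the 4 arrays with the mutant in Cy5 alone (4633 at an unadjusted p below 0.05). The 4 arrays with the mutant in Cy3 alone gave 6817. On simulated data of this size the test recovered none of 67 probes changed 2-fold among few changed ones, and 77.4% where a large part of the array was changed.

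Neuron, synaptic vesicle, mitochondrial respiratory chain and ribosomal protein lists had mean ratios above those of other genes with a preset correlation of 0.01 between genes, and none of the 4 passed with an estimated correlation (adjusted p = 0.484 for each). Of 16 measured neuron markers, 11 were positive and past the threshold and none negative, with a median 0.83 above that of all genes (camera, adjusted p = 5.81e-06). Uchl1, the ubiquitin hydrolase of neurons, stood at 0.97 ± 0.141. Of 19 synaptic vesicle genes, 12 were positive and 3 negative (adjusted p = 2.39e-05), led by Syp, synaptophysin, at 0.97 ± 0.14 and Vamp1 at 0.97 ± 0.133. Of 62 genes of the mitochondrial respiratory chain, 32 were positive and 1, Ndufb7 (-1.27 ± 0.209), negative (adjusted p = 2.01e-13). Of 58 genes of the cytosolic ribosomal protein list, 33 were positive and 2 negative, Rpl39l (-2.12) and Rps19bp1 (-0.54) (camera, adjusted p = 1.02e-11). The list was picked by symbol, and Rps19bp1 is not itself a ribosomal protein gene. Adjusted over the list alone, 11, 16, 37 and 39 members of these lists passed. Among all 8604 genes 2478 passed (28.8%), 976 positive and 1502 negative. Counts for each list stand against that share.

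The same held for 7 of 16 astrocyte markers, all positive (adjusted p = 0.00123), with Glul, glutamine synthetase, at 1.09 ± 0.137, and for 6 of 11 forebrain glutamatergic markers, all positive (adjusted p = 0.00123), with Lmo4 at 0.90 ± 0.129. Heat shock and unfolded protein response genes had 8 positive and 2 negative members of 24 (adjusted p = 0.00632). GABA genes had 4 positive and 1 negative of 9, with Slc6a11, a GABA transporter, at 0.80 ± 0.119 and Gad1, which synthesises GABA, at -0.93 ± 0.119 (adjusted p = 0.0259). AMPA receptor auxiliary and scaffold genes had 5 positive and 1 negative of 20 (adjusted p = 0.0259), with Camk2a at 0.87 ± 0.166 and Dlg2 at -1.26 ± 0.21. Adjusted over the list alone, 10, 9, 13, 5 and 6 members of these lists passed. These were the 9 lists of 31 past the threshold, and all 9 lost it with an estimated correlation between genes (lowest adjusted p = 0.484). With runs of 48 spots centred, the forebrain glutamatergic, GABA and AMPA receptor lists lost it (adjusted p = 0.129, 0.242 and 0.284).

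No other list passed in the mean ratio, and several of them had a share of called members near the 28.8% of all genes. RNA editing enzymes had 1 positive call of 7, Adar (0.51 ± 0.134), the other catalytic editing enzyme of brain, and 3 negative ones, among them Adarb2, its relative without known activity, at -1.12 ± 0.131 (list adjusted p = 0.36). Transcripts with coding sites edited by ADAR enzymes had 3 positive and 3 negative calls of 13, with the potassium channel Kcna1 at 1.0 ± 0.14, Cyfip2 at 0.92 ± 0.138 and the calcium channel Cacna1d at -1.09 ± 0.302 (list adjusted p = 0.244). Ionotropic glutamate receptors had 2 positive and 1 negative of 8, with Gria1 at 0.76 ± 0.116 and Grik4 at -1.61 ± 0.277 (list adjusted p = 0.249). Metabotropic receptors and glutamate transporters had 1 of 7, Slc1a3 (0.82 ± 0.155, list adjusted p = 0.154). Interferon response and double-stranded RNA sensing genes had 1 positive call of 20, Tap1 (0.88 ± 0.148), and 5 negative ones (list adjusted p = 0.0674). Among the latter were Ifi35 at -1.10 ± 0.165 and Psmb8 at -0.99 ± 0.135. Serotonin and catecholamine genes had 5 negative of 10, with Ddc, which makes dopamine and serotonin, at -1.40 ± 0.233 and Slc18a2 at -1.28 ± 0.276 (list adjusted p = 0.0609). Adjusted over the list alone, 5, 6, 5, 1, 8 and 5 members of these lists passed.

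Among the remaining cell type lists, oligodendrocyte and myelin markers had 4 positive and 1 negative of 11 (adjusted p = 0.0596), with Cnp at 0.92 ± 0.143 and Qdpr at 0.76 ± 0.124. Microglia markers had 1 positive call of 10, C1qb (0.78 ± 0.134), and 3 negative ones (adjusted p = 0.907). Among the latter were Aif1 at -1.12 ± 0.153 and Ptprc at -1.05 ± 0.164. Blood cell markers had 1 positive call of 8, Hba-a1 (0.78 ± 0.126), and 5 negative ones (adjusted p = 0.125). Here S100a8 stood at -1.67 ± 0.178 and the erythroid heme enzyme Alas2 at -1.40 ± 0.206. Choroid plexus and ependyma markers had 1 positive call of 11, Ttr (0.71 ± 0.114), and 4 negative ones (adjusted p = 0.237). Trpv4 stood at -1.09 ± 0.206 and Igfbp2 at -1.04 ± 0.235. Striatal markers had 2 positive and 1 negative of 11 (adjusted p = 0.249), with Penk at 0.81 ± 0.144 and Ppp1r1b at 0.78 ± 0.124, and thalamic and midbrain markers 2 and 2 of 9 (adjusted p = 0.492). Hypothalamic neuropeptides had 2 positive of 7 (adjusted p = 0.239), Cck at 0.69 ± 0.126 and Sst at 0.54 ± 0.13, and cerebellar markers 1 of 8, Cbln1 at 0.42 ± 0.117 (adjusted p = 0.0963). Endothelial and pericyte markers had 1 positive and 1 negative of 11 (adjusted p = 0.782), Cdh5 at 0.66 ± 0.121 and Pecam1 at -1.62 ± 0.326. Of the pituitary hormones 1 of 5 was past the threshold, Prl at -1.06 ± 0.259 (adjusted p = 0.569), and its sign turned to 0.13 on the arrays with the mutant in Cy5 alone. Adjusted over the list alone, 6, 4, 6, 6, 3, 5, 2, 0, 2 and 1 members of these lists passed.

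The last lists had mixed signs or few calls. Immediate early genes had 2 positive and 1 negative of 15 (adjusted p = 0.255), with Homer1 at 0.62 ± 0.138 and Btg2 at -0.87 ± 0.242. Circadian clock genes had 2 positive and 1 negative of 14 (adjusted p = 0.244), with Dbp at 0.64 ± 0.181 and Csnk1e at -1.18 ± 0.16. Glucocorticoid-responsive genes had 2 positive and 3 negative of 11 (adjusted p = 0.95), with Sult1a1 at -2.34 ± 0.583 and Plin4 at -0.87 ± 0.173. Cholesterol synthesis genes had 1 positive and 2 negative of 12 (adjusted p = 0.777), with Hmgcs1 at 0.70 ± 0.15 and Mvk at -2.07 ± 0.584. Voltage-gated potassium channels had 3 and 3 of 13 (adjusted p = 0.777), with Kcnd3 at -1.25 ± 0.186, and calcium and sodium channels had 1 of 14, Cacna1d (adjusted p = 0.36). Adjusted over the list alone, 2, 1, 8, 2, 8 and 0 members passed. For glucocorticoid-responsive genes, endothelial and pericyte markers and pituitary hormones, the list's mean, median and test differed in sign. Over all lists, 197 of 447 measured genes passed, 144 with a positive and 53 with a negative mean ratio.

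For the swap component, named genes came from probes past the threshold with the same sign on all 8 arrays once medians were subtracted and the arrays with the mutant in Cy3 had their sign turned. Within these, Sun5, a protein of the sperm neck, had the largest positive value, 1.23 ± 0.134 (SE, n = 4). Tsga10, a testis protein, had 1.16 ± 0.134, and Tekt2, a tektin of flagella, had 1.01 ± 0.12. Hsd11b1, the enzyme that regenerates active glucocorticoid, had 1.18 ± 0.126, and the signal protein Dhh 1.16 ± 0.146. On the negative side stood Kif5c, a neuronal kinesin, at -0.84 ± 0.138, Eif3f, a translation initiation factor, at -0.99 ± 0.187, Rab11a, of recycling endosomes, at -0.77 ± 0.144, and Sdha, of succinate dehydrogenase, at -0.77 ± 0.113. The 24 genes named for this component had adjusted p between 0.0383 and 0.0442 with array medians subtracted and between 0.0591 and 0.065 as deposited (limma).

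The other positive genes were Fam53b (1.20), Pde1a (1.09), Gpc6 (1.02), Npas3 (0.98), Flacc1 (0.96), Wwox (0.95) and Iqcf4 (0.94). The other negative ones were Bzw1 (-1.19), Dcaf8 (-1.18), Lztr1 (-0.84), Fkbp2 (-0.81), the lysosomal cholesterol carrier Npc2 (-0.78), Sh3glb1 (-0.77), Ccdc92 (-0.76) and the microtubule tip protein Clip1 (-0.75). As deposited, limma called 0 of 18797 probes in the swap component (5785 at an unadjusted p below 0.05, and 3 by a plain one-sample test). With the probes of a gene averaged, 286 of 8107 genes passed as deposited, 87 positive and 199 negative. With medians subtracted 755 genes passed, and 0 once the trend on the mean ratio was also removed. With array medians subtracted limma called 1473 probes, 265 positive and 1208 negative, a setting chosen after the data were seen. All 24 genes named here kept their sign and lost the threshold in every alternative run: as deposited, without any 1 mouse, with the trend on the mean ratio removed, with runs of 48 spots centred, with arrays scaled to one spread, with quantile normalisation and with the sets of mice as a block. They were selected for one sign on all turned arrays, so for runs without 1 mouse the sign was largely fixed in advance.

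**Figure D3:**
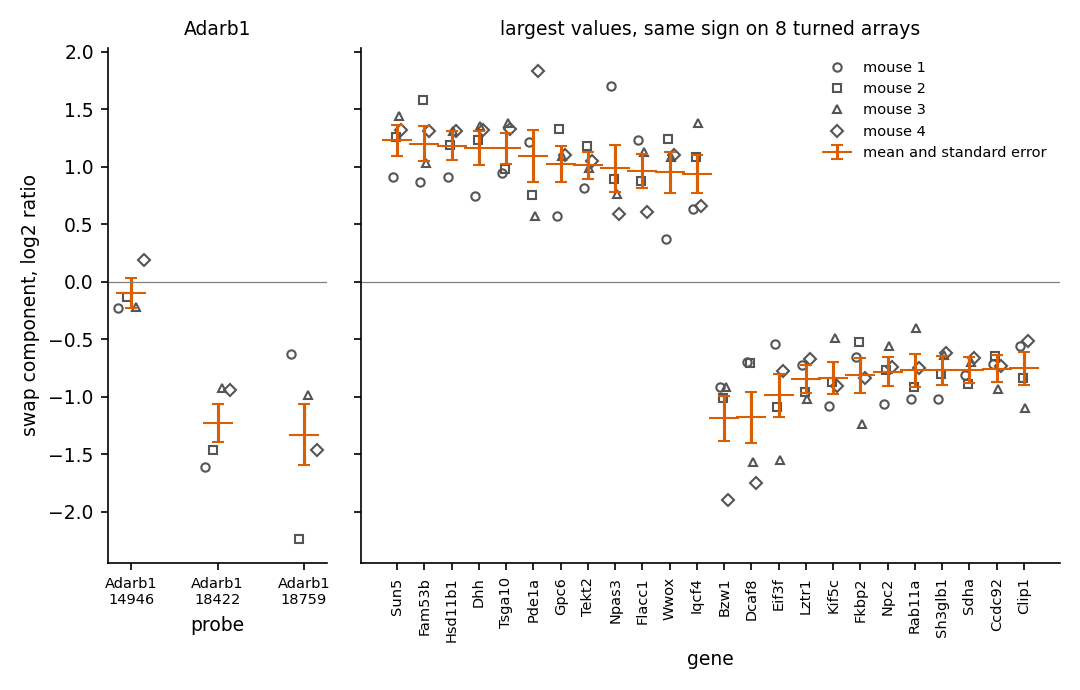
Swap component with array medians subtracted, in log2 units (vertical axis), for the 3 Adarb1 probes (left) and for the 12 genes with the largest positive and the 12 with the largest negative values (right), among probes past the threshold with the same sign on all 8 arrays after the sign was turned for the mutant in Cy3. Symbols are the 4 mice and bars are means with moderated standard errors. Adarb1 probes 18422 and 18759 lie at -1.23 and -1.33, below each of the named negative genes, and probe 14946 lies at -0.10. The Adarb1 probes are shown whatever their signs, and probes 18422 and 18759 did not keep one sign on all 8 turned arrays.

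With the preset correlation, 10 lists, among them neuron, astrocyte and respiratory chain genes, had lower swap components than other genes. None of them passed with an estimated correlation (lowest adjusted p = 0.459) or after the trend on the mean ratio was removed (lowest adjusted p = 0.108). Of 62 respiratory chain genes, 16 were negative and past the threshold and 1 positive (camera with array medians subtracted, adjusted p = 1.35e-06). Of 15 neuron markers 7 were negative, among them Chn1 (-0.88 ± 0.104), and of 19 synaptic vesicle genes 8, among them Syp (-0.80 ± 0.124), with an adjusted p of 0.000214 for each list and none positive. Astrocyte markers had 4 negative of 16, with Sparcl1 at -0.74 ± 0.123 (adjusted p = 0.00236), forebrain glutamatergic markers 5 of 11, with Lmo4 at -0.68 ± 0.106 (adjusted p = 0.00846), and cerebellar markers 4 of 8, with Cbln1 at -0.53 ± 0.116 (adjusted p = 0.00896). Heat shock genes (7 of 24, adjusted p = 0.015) and AMPA receptor auxiliary and scaffold genes (2 of 19, adjusted p = 0.0366) were also lower. So were the ribosomal protein list (15 negative and 1 positive of 56, adjusted p = 0.0368) and circadian genes (4 of 14, adjusted p = 0.0484). Adjusted over the list alone, 35, 10, 10, 10, 5, 5, 10, 7, 30 and 5 members of these lists passed. Among all 8107 genes 755 passed in this setting (9.31%), 111 positive and 644 negative.

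Pituitary hormones (adjusted p = 0.0368), with Prl at 1.09 ± 0.444, and serotonin and catecholamine genes (adjusted p = 0.029), with Ddc at 0.97 ± 0.345, were higher as lists, with no member past the threshold over all genes and 1 and 0 adjusted over the list alone. Transcripts with edited coding sites had 3 negative calls of 13 and RNA editing enzymes 1 of 6. Both lists missed the threshold (camera, adjusted p = 0.0696 and 0.459). The call among the editing enzymes was Adarb1, the disrupted gene, which is also 1 of the 3 in the other list. Averaged over its 3 probes, Adarb1 had a swap component of -0.89 ± 0.134 (limma, medians subtracted, adjusted p = 0.0271). The pituitary hormone and the serotonin and catecholamine lists also lost the threshold with an estimated correlation (adjusted p = 0.598 and 0.459) and with the trend removed (adjusted p = 0.126 and 0.168). Of the 12 lists, 8 also passed in the mean ratio, each with the opposite sign. Values spread more with the mutant in Cy3 (standard deviation 0.904 across probes, against 0.521 in Cy5). This alone sets a high mean ratio against a low swap component, so the opposite signs are no separate result. With arrays scaled to one spread, 0 lists passed in the swap component.

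**Figure D4:**
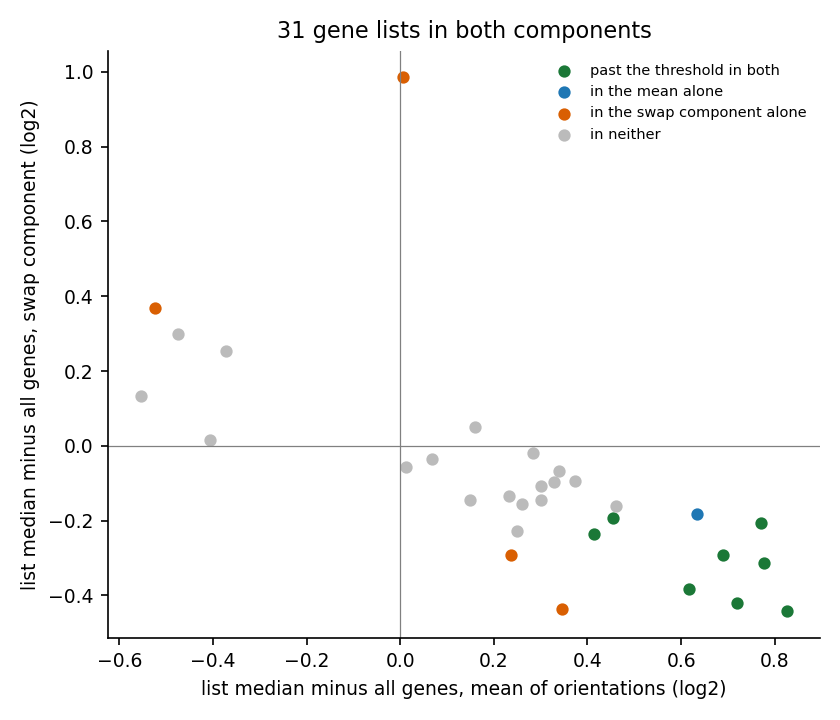
Median log2 value of each of 31 gene lists minus that of all genes, for the mean ratio (horizontal axis) and the swap component with array medians subtracted (vertical axis); colours show in which component the list passed the camera test. The 8 lists past the threshold in both lie in the lower right, positive in the mean ratio and negative in the swap component.

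Genes near Adarb1 and Gria2 were compared with genes elsewhere, since targeted alleles can carry flanking sequence of another strain. In the mean ratio, 58 of 207 genes within 20 Mb of Adarb1 passed (28%, against 28.8% elsewhere), and 51 of 181 genes near Gria2 (28.2%, against 28.8%). Permutation over windows of neighbouring genes gave one-sided p of 0.689 and 0.671. In the swap component with medians subtracted, a setting chosen after the data were seen, 21 of 197 genes near Adarb1 passed (10.7%, against 9.27%, permutation p = 0.402) and 10 of 174 near Gria2 (5.75%, against 9.38%, permutation p = 0.966). With the trend removed, 0 passed near either locus and 0 elsewhere.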

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

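Apart from the count of sign patterns, the tests in this part were chosen after the patterns were seen; for the spots coded for an empty denominator the expected direction was written before that value was known, but after empty cells had been compared, a comparison it replaced. Of 118 sets of values examined, 4 held a mouse far from the others, where chance gives about 1 in 20. For Acbd3 probe 15519, mouse 1 had a mean ratio of -6.44, far below the other mice. For Adarb1 averaged over its probes, mouse 1 had a mean ratio of -0.50, below the others. For Alas2, mouse 4 stood apart at -2.11. For Bzw1 probe 14427, mouse 4 stood apart in the swap component at -1.90.

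The 6105 probes past the threshold in the mean ratio are the first pattern. Of the 8 sign patterns of the 4 mice, 1 gave as many probes, the real one, and the highest other count was 0, but 8 patterns are too few for a share under 0.05. A bias that depends on spot signal is a candidate explanation: 46 probes coded for an empty denominator, which selects for a high ratio, differed by -0.797 ± 0.142 (SE) from other probes in the mean of the other orientation, and the replaced comparison gave -0.542 and -0.601 but decides nothing, since an empty cell may select for a low ratio. With so few probes, and since an RNA difference would also turn the sign if the ratios were Cy5 over Cy3, this does not single out the bias. A difference between mutant and pool RNA was examined through Adarb1, of which 0 of 3 probes passed as deposited and 1 with medians subtracted, and the genotype stays among the open explanations.

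The second pattern is the shift of 12 gene lists in the swap component. After the trend on the mean ratio was removed, 0 lists passed, so a trend of the swap component on the mean ratio may account for them. The median of the respiratory chain list moved from -0.37 to -0.09 and that of the neuron markers from -0.52 to -0.06. A difference between mutant and pool RNA in the same transcripts cannot be told apart from this trend, since the lowest adjusted p after removal was 0.108 and the removal also takes away any true change that follows the mean ratio.

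The third pattern is Adarb1 in the swap component. Removal of the trend left 2 of 3 probes among the lowest 1% of 18797 probes, at ranks 11 and 72. By chance 0.03 are expected, but these probes had been seen at ranks 4 and 8 beforehand, so that number is no yardstick. The values that remained argue against that trend as the whole cause. Probe 18422 moved from -1.23 ± 0.163 to -0.91 ± 0.134 and probe 18759 from -1.33 ± 0.267 to -1.23 ± 0.325. Their calls ended (adjusted p = 0.138 and 0.233, limma) in a fit that called no probe at all. A lower level of Adarb1 in the mutants is consistent with 2 of 3 probes past the threshold with medians subtracted, but probe 14946 (-0.10) did not show it and the direction of the ratios is open.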

How the results depend on the processing

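Alternatives outside the planned ones were chosen after the data were seen. The count of probes past the threshold in the mean ratio (6105) became 0 with the mutant in Cy5 alone, 0 in mice 1 and 2 alone and 0 in mice 3 and 4 alone (7164 and 7553 at an unadjusted p below 0.05), 2274 with a plain one-sample test, and 905 after the less variable probes were dropped. That filter removes probes with the smallest spread between arrays, which the test favours, so a fall was built in. With genes as units, 2478 of 8604 passed, 28.8% in place of 29.6% of probes. Without 1 mouse the count of probes ranged from 0 to 3926, and without 1 array from 1064 to 6166. The percent of positive calls (37.4) became 56.1 with medians subtracted and 58.1 with runs of 48 spots centred, and ranged from 5.45 to 43.1 without 1 mouse or array. With the mouse as a replicate block in fits of the 8 arrays, the count was 7983, and 7487 with a dye term; the within-mouse correlation was -0.138 and 0.18. The 9 lists past the threshold became 4 with the mutant in Cy5 alone (12 in Cy3 alone), 6 with runs of 48 spots centred, 0 with names at the same spot number and 0 with an estimated correlation. The fry test, which sets a list against no change and not against other genes, called 10 lists in one direction and 30 in either direction.

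The 0 probes called in the swap component became 1473 with medians subtracted and 3 with a plain one-sample test, and 286 with genes as units. Its 12 lists became 0 with an estimated correlation, 0 after trend removal, 0 with names at the same spot number, 4 with runs centred and 0 with arrays scaled to one spread. The same-mouse correlation (0.133) was 0.0264 within sets of mice, or 0.0464 by Spearman. The locus comparisons kept their side of the threshold.

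Of 106 named results past the threshold, 105 kept their sign under every alternative run and 0 kept the threshold under all. Prl turned to 0.131 with the mutant in Cy5 alone. The genes and unnamed spots with the largest mean ratios had been selected for one sign on all arrays. So had the genes named for the swap component, apart from Adarb1. For them the sign in runs with fewer mice or arrays was largely fixed in advance. The robust test and the block fits left estimates as they were or nearly so. A kept sign in these runs is therefore little evidence of stability. All 106 lost the threshold without mouse 2, 3 or 4, and 41 without mouse 1. Where a cause is not evident from fewer mice, arrays or genes, the cause was not tested. No intensities were used, so signal over background sets no limit that can be stated here.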

Other observations

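In this part, the tests on the swap component, on displaced spots and on the sets of mice were added after the data were seen, except the test of weak signal and those of the set difference, which were fixed before their results were known. Cyfip2, whose transcript holds a coding site edited by ADAR2, and Kcna1, edited in the same way, had mean ratios of 0.92 and 1.0. In the same list Cacna1d (-1.09), Ube2o (-0.94) and Azin1 (-0.72) were negative and past the threshold, and the list as a whole did not pass (adjusted p = 0.244). In the swap component Kcna1 stood at -0.58 ± 0.114 (SE, n = 4, adjusted p = 0.0355, limma, medians subtracted). Zic1, a transcription factor of cerebellum and thalamus, stood there at -0.77 ± 0.105 (adjusted p = 0.0271), while its mean ratio of 0.69 ± 0.2 missed the threshold (adjusted p = 0.051). Cck, a neuropeptide, stood at -0.66 ± 0.1 and Cnp, of myelin, at -0.71 ± 0.114 (both limma adjusted p = 0.0271). Once the trend on the mean ratio was removed, 0 genes passed in the swap component.

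Genes within 20 Mb of Adarb1 had a median absolute swap component of 0.291 against 0.239 elsewhere (permutation over 4185 windows, one-sided p = 0.0055, 0.088 adjusted over the 16 window tests computed). After removal of the trend the values were 0.172 and 0.169 (permutation p = 0.473). Near Gria2 the corresponding values after removal were 0.191 and 0.168 (permutation p = 0.0588, 0.47 adjusted).

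The hypothesis that the spots are displaced against the annotation was tested on the disagreement of probes of a gene at the same spot number, after that disagreement was seen. The Spearman correlation reached 0.274 at a shift of 11, which is consistent with a displacement. The other explanation, weak signal on most spots, was tested beforehand: among the least variable probes at the same spot number rho was 0.0654 (95% interval -0.0591 to 0.194, 268 genes), which decides nothing. With the shift, rho among the least variable probes was 0.484 (288 genes). Of 365 genes with 2 probes past the threshold in the mean ratio, 286 (78.4%) had the same sign, against 50.8% from the shares of signs alone.

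Arrays of mice 1 and 2 and of mice 3 and 4 resembled each other more within than between these sets. With the mutant in Cy3, correlations across probes were 0.583 and 0.677 within sets and 0.425 to 0.519 between them. The difference between the sets correlated at 0.281 between the orientations. Between 2 probes of a gene it was unrelated, with rho at 0.00692 (95% interval -0.0333 to 0.0483), and with names at the same spot number rho was -0.0108. Runs of 48 consecutive spots took up 15.8% of the variance of the set difference, 15.5% of that of the mean ratio and 10.6% of that of the swap component. The means of the orientations correlated at 0.529 across 18797 probes, with a standard deviation of 0.521 with the mutant in Cy5 and 0.904 with the mutant in Cy3.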
